A study of Mus musculus with 6 samples.

How the data were processed

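Messenger RNA levels were measured by RNA sequencing in 6 libraries of GBM8401, a human glioblastoma cell line. The titles name 3 libraries as control and 3 as siINTS9, and the groups were taken from these titles. Elsewhere the labels give scramble siRNA for the control group and siRNA against INTS9 for the other. Per the labels' protocols, RNA was extracted with TRIzol, had RNA integrity numbers between 9.6 and 10.0, and was made into libraries with a SMARTER mRNA-Seq kit. The labels hold contradictions that bear on the reading of the files. They name the mouse as the organism, and the submitters' processing notes name the mouse builds GRCm38 and mm10, while all 21462 listed genes carry human Ensembl identifiers. The growth and treatment text in the labels speaks of another glioblastoma line, U87MG, and of metformin, which the titles and treatment fields do not mention. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

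Each library came as a table of 21462 genes with a symbol, a position, an identifier and 4 values. The deposited counts are whole numbers per gene, per the file headers total counts, and no gene had a negative or broken value. The aligner, the counting program, the annotation and the use of strand in counting are not given in the sources used here, and the human genome build behind the positions is not named. The deposited RPKM values are counts scaled by gene length and library total, and the whole-number library total behind them was recovered from the 13 mitochondrial genes, whose exons fill their listed positions. Deposited TPM values were used as an alternative unit. The deposited CPM column is a scaled score rather than plain CPM, since its sums ran from 935539 to 1032028 while each column stayed proportional to the counts. Reads included in the RPKM total but not counted on a listed gene were not analysed here beyond their share. The reference supplied with the files was a mouse genome and was not used, so GC content was not examined.

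Total counts on listed genes were 19092210, 20651870 and 20115503 in control replicates 1 to 3 and 3083846, 21135012 and 14215739 in siINTS9 replicates 1 to 3. A gene at 10 CPM thus rests on far fewer counts in siINTS9 replicate 1 than elsewhere. Intervals on counts are exact Poisson or exact binomial intervals at the 95% level and cover counting error alone, since no molecular identifiers are recorded. No pair of libraries was identical. Over genes with at least 20 counts in a pair, chi-square per degree of freedom was 3.55 between control replicates 2 and 3. It was 2.57 between siINTS9 replicates 2 and 3. Against its group's replicates 2 and 3, control replicate 1 gave 17.4 and 13.7, and siINTS9 replicate 1 gave 29.5 and 26.8. Pairs of a control library with siINTS9 replicate 2 or 3 gave 13.9 to 20.0. Control replicate 1 thus also stood apart in its group, and every library was counted as its own sample.

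Genes were kept with edgeR's filterByExpr, scaled with TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on all 6 libraries with no covariate. P-values were adjusted by Benjamini-Hochberg over the 12256 genes kept, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic of that test. CPM values in the text are counts scaled here by TMM library sizes. Those from the fit are not on the scale of the deposited CPM column. The summed and plotted histone CPM values used TMM factors over all listed genes, without the filter. These histone values lie on the scale of the deposited CPM column. In all, 39 gene lists were fixed before the data were examined. The 34 lists with at least 5 genes tested were compared with all other genes by camera on voom values (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over lists. Genes were named by a rule fixed before the data were examined. It takes INTS9 and all measured Integrator genes, and the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose mean is at least 10 CPM. From each list it takes up to 2 called members per direction, or else up to 2 members with the smallest p. Members named from the fit without siINTS9 replicate 1 were chosen after the data were seen. Some list members that passed are not reported here.

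On simulated counts drawn from the means and dispersions of all 6 libraries (12147 genes), with 200 genes changed by known folds and the 38 mitosis genes lowered together 1.5-fold, the test recovered 22% of 1.5-fold and 75% of 2-fold changes among the 200, with 3 false calls among 11911 unchanged genes. Simulating the 5 libraries without siINTS9 replicate 1 (12253 genes) gave 77% and 89%, with 10 false calls among 12016. Each setting was simulated in a single draw. Genes were drawn independently, with the same dispersion per gene in all libraries and no systematic deviation of siINTS9 replicate 1. These rates therefore need not hold for the real libraries. Alternatives covered the replicate number as a block, leaving out each library, RLE and library-size scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, limma on log2 of the deposited TPM or CPM plus 1, minimum fold changes, camera with an estimated correlation, and fry. Library weights, and other tools without siINTS9 replicate 1, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.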

Results

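Gene expression was compared between 3 GBM8401 libraries given scramble siRNA and 3 given siRNA against INTS9, a subunit of Integrator, the nuclear complex that cleaves the ends of small nuclear RNAs and terminates transcription. GBM8401 is a human glioblastoma line, and all 21462 listed genes carry human identifiers although the labels name the mouse. The labels give its genotype as IDH mutant. The design text asks which genes differ between the control and siINTS9 cells. Total counts per library on listed genes ranged from 19092210 to 20651870 in the control group. In the siINTS9 group they were 3083846, 21135012 and 14215739. The share of the library total on listed genes was 11.1% in siINTS9 replicate 1 and between 85.3% and 89.6% in the other 5 libraries. Because that library stands apart, results are given with and without it where it matters. Control replicate 1 also differed from control replicates 2 and 3 in its counts, and both of these fits keep it.

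INTS9 fell in the siINTS9 group. Its level was 14.5 ± 0.974 CPM (SD, n = 3) in control libraries and 5.02 ± 0.581 CPM (SD, n = 3) in siINTS9 libraries, or 0.357 times the control level. The log2 fold change was -1.48 ± 0.13 (SE), with an adjusted p of 0.0333 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Per library, INTS9 stood at 15.5, 13.6 and 14.5 CPM in control replicates 1 to 3 and at 4.36, 5.30 and 5.41 CPM in siINTS9 replicates 1 to 3. The value of siINTS9 replicate 1 rests on 14 counts, with a 95% exact Poisson interval of 7.65 to 23.5 counts. INTS9 (ENSG00000104299) lies on the minus strand of chromosome 8 from 28767661 to 28890242, as the files give it, and the build of these positions is not named. The log2 fold change was -1.45 without siINTS9 replicate 1, with an adjusted p of 0.00169. Leaving out control replicate 1, 2 or 3 or siINTS9 replicate 2 or 3 kept the log2 fold change between -1.44 and -1.54, while the adjusted p lay between 0.170 and 0.288.

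**Figure D1:**
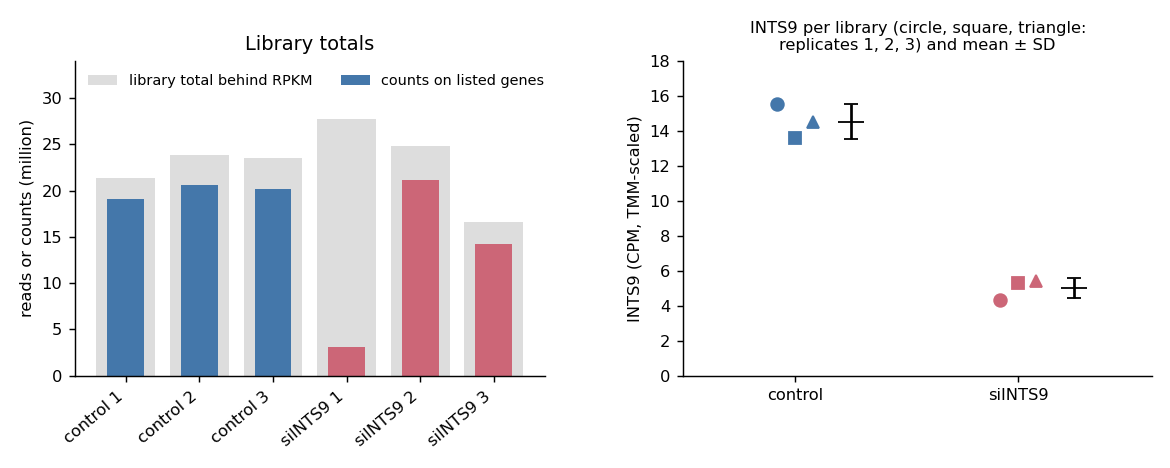
Left, for each of the 6 libraries, the library total behind RPKM (grey, in units of 1e6 reads) and the counts on listed genes (coloured), with siINTS9 replicate 1 at 3083846 counts of 27734068. Right, INTS9 in TMM-scaled CPM per library, with the mean and SD of each group, all 3 siINTS9 libraries below all 3 control libraries.

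Of the 21 Integrator genes tested, INTS9 alone was called over all genes tested. Adjusted over the list alone, INTS9 and INTS10 fell. INTS10, another subunit, had a log2 fold change of -0.45 ± 0.092 (SE) and an adjusted p of 0.0729 over all genes, and without siINTS9 replicate 1 it fell by 0.41 on the log2 scale with an adjusted p of 0.0132. INTS11, the endonuclease that pairs with INTS9, stood at 38.7 ± 1.97 CPM in control and 32.6 ± 0.287 CPM in siINTS9 libraries (SD, n = 3 each; log2 -0.25, adjusted p 0.184). INTS1 stood at 149 CPM in both groups, and INTS4 and INTS8 had log2 values of 0.014 and 0.0011. Camera placed the list lower in the siINTS9 libraries at an adjusted p of 0.0362 with the preset correlation, and the adjusted p was 0.490 with an estimated correlation. This call was lost without siINTS9 replicate 1 (camera's adjusted p 0.0582). The list holds INTS9, the target of the siRNA, and was not tested without it, so the call does not stand for the other subunits.

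Across the transcriptome, 119 of 12256 genes were called by edgeR's quasi-likelihood test, of which 71 rose and 48 fell. In all 119, the 3 siINTS9 libraries lay on the same side of the 3 control libraries. The count without siINTS9 replicate 1 was 1426 of 12340 genes tested, 704 higher and 722 lower, and it included all 119 in the same direction. Called list members in that fit are to be read against this share. Genes whose groups do not overlap numbered 3781, or 30.9% of those tested, against 10% on average if the libraries were exchangeable. Genes are not independent and the share was not computed for other splits, so its spread by chance is not known. Leaving out any of control replicates 1, 2 and 3 or siINTS9 replicates 2 and 3 gave 0 calls, with 1389 to 2033 genes at an unadjusted p under 0.05. DESeq2 on all 6 libraries called 782 genes.

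The largest rise under the naming rule was in TP53INP1, a p53-induced regulator of stress responses and autophagy, from 10.7 ± 1.40 to 26.9 ± 2.05 CPM (SD, n = 3 each; log2 1.31 ± 0.13 SE, adjusted p 0.0333). TP53INP1 (ENSG00000164938) is listed on the minus strand of chromosome 8 from 94925972 to 94949378. LAMC1, a laminin chain of basement membranes, rose from 184 ± 14.6 to 390 ± 56.7 CPM (SD, n = 3 each; log2 1.08, adjusted p 0.0333). ADAM12, a membrane metalloprotease, rose by a log2 of 1.06, FBN1, the microfibril protein fibrillin, by 1.03, and LOX, which crosslinks collagen, by 0.92. The zinc-finger proteins KLF9 and ZNF35 rose by log2 values of 1.10 and 1.01. KLHL24, an adaptor of a ubiquitin ligase, rose by 1.11 and ZSWIM4 by 1.02. ARHGAP18, KIAA1324 and ARRDC3, an arrestin-domain protein, rose by 0.96, 0.89 and 0.88.

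The largest fall under the rule was in PHLDA1, a pleckstrin-homology-like protein, from 239 ± 8.04 to 106 ± 15.2 CPM (SD, n = 3 each; log2 -1.18 ± 0.12 SE, adjusted p 0.0333). PHLDA1 (ENSG00000139289) is listed on the minus strand of chromosome 12 from 76025447 to 76033932. INTS9 fell further but its mean lies below the floor of 10 CPM. EXOSC3, a core subunit of the RNA exosome, had a log2 fold change of -0.95, as did IL12A, a subunit of interleukin-12. RRM2, the small subunit of ribonucleotide reductase, fell from 368 ± 18.3 to 220 ± 5.20 CPM (SD, n = 3 each; log2 -0.74 ± 0.087 SE, adjusted p 0.0333). GDF15, a secreted stress-responsive factor, and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, both had a log2 of -0.76. SCML1 stood at -0.84, and both CIPC, a repressor of the circadian clock, and RNH1, the ribonuclease inhibitor, stood at -0.79. FAM107B and CLDND1 had a log2 of -0.74 and SRPRA, a subunit of the signal recognition particle receptor, one of -0.73. TP53INP1, LOX, KIAA1324, EXOSC3, CIPC, PCK2, CLDND1 and SRPRA overlap other listed genes, and with the use of strand not given their counts are uncertain to that extent.

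**Figure D2:**
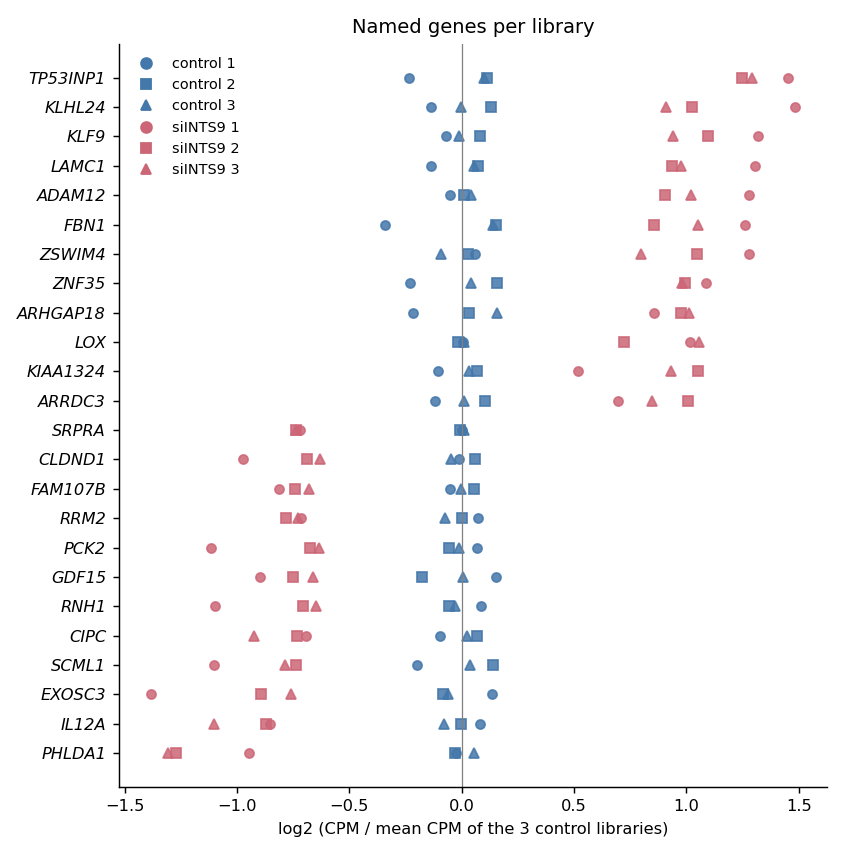
For the 24 genes named by the rule, log2 of the CPM over the mean CPM of the 3 control libraries, in each of the 6 libraries (blue control, red siINTS9; circle, square and triangle for replicates 1 to 3). The siINTS9 points of each gene lie on the same side of all 3 control points.

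Genes of DNA replication were lower together. Of 42 tested, RRM2 fell and none rose over all genes tested, 14 fell when adjusted over the list alone, and 41 had a fold change below 0, with a median log2 of -0.28. With siINTS9 replicate 1 left out, 20 fell and none rose, with a median of -0.24. These included RRM2 (-0.76), CCNE2 (-0.59), which drives entry into S phase, and MCM2 (-0.28), MCM3 (-0.30), MCM4 (-0.26), MCM5 (-0.24), MCM6 (-0.31) and MCM7 (-0.24), the subunits of the replicative helicase. The list was placed lower by camera at an adjusted p of 6.56e-12 with the preset correlation, and the adjusted p was 0.418 with an estimated correlation. DNA repair genes had a median log2 of -0.20 over 33 genes, of which 29 lay below 0, and none was called over all genes tested. Adjusted over the list alone, FANCI of the Fanconi anaemia pathway fell (log2 -0.42), and without siINTS9 replicate 1, 9 genes fell, with FANCE at -0.41 and FANCI at -0.40. For repair, camera gave an adjusted p of 6.38e-06 with the preset correlation and 0.418 with an estimated correlation. Among 38 mitosis genes none was called, the median was -0.15, and camera's adjusted p was 0.00825 with the preset correlation and 0.680 with an estimated correlation. No mitosis gene passed when adjusted over the list alone. Leaving out siINTS9 replicate 1, the mitosis median was -0.050 and 5 genes fell, led by NUF2 and KIF2C at -0.30 each. In that fit camera no longer called the list (adjusted p 0.135).

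Targets of p53 lay above 0 in 20 of 25 genes tested, with a median log2 of 0.24. TP53INP1 and BTG2 (log2 0.61), an antiproliferative gene, rose and GDF15 fell (-0.76). Adjusted over the list alone, 6 rose and 1 fell. In the 5 libraries without siINTS9 replicate 1, 10 rose and 1 fell. CDKN1A, the cyclin-dependent kinase inhibitor p21, was among these 10 rises (0.53) and had a log2 of 0.51 and an adjusted p of 0.0648 with all 6 libraries. Camera gave an adjusted p of 3.62e-04 with the preset correlation and 0.418 with an estimated correlation.

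Extracellular matrix and mesenchymal genes lay above 0 in 29 of 33 tested. LOX, COL5A1 (log2 0.79), a fibrillar collagen chain, and MMP14 (0.51), a membrane-bound matrix metalloprotease, rose and none fell. When adjusted over the list alone, 8 rose and none fell. Apart from siINTS9 replicate 1, 9 rose, including SNAI2 (0.94), a transcription factor of mesenchymal transition. Camera's adjusted p was 2.13e-05 with the preset correlation and 0.418 with an estimated correlation. The 4 fibroblast markers tested also lay above 0, with a median log2 of 0.37, none called over all genes tested and 2 higher when adjusted over the list alone. Of 19 targets of TGF-beta, TGFBR1, its type I receptor, rose (log2 0.67), and 4 rose when adjusted over the list alone. Of these targets, 6 rose without siINTS9 replicate 1, among them TGFBI (0.44). The TGF-beta list had an adjusted p of 3.62e-04 with the preset correlation and 0.570 with an estimated correlation. ITGA6, a laminin-binding integrin on the list of neural stem cell genes, rose (0.82), while ALDH1A3, an aldehyde dehydrogenase of the same list, fell (-0.71). Among 15 stem cell genes 2 rose and 1 fell when adjusted over the list alone. IGFBP3, a secreted binder of insulin-like growth factors, rose (0.94) among 20 YAP targets, of which 1 rose and 2 fell when adjusted over the list alone.

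WIPI1 (log2 0.89), a protein of autophagosome formation, and the lysosomal membrane proteins LAMP2 (0.66) and LAMP1 (0.48) rose among 28 autophagy and lysosome genes, and none fell. When adjusted over the list alone, 4 rose and 3 fell. Setting siINTS9 replicate 1 aside, 7 rose and 3 fell, ATG7 and SQSTM1 among the latter at -0.41 and -0.33. That list was not called by camera with all 6 libraries (adjusted p 0.184), but was placed higher without siINTS9 replicate 1 (adjusted p 0.0240; adjusted p 0.685 with an estimated correlation). BNIP3L, a mitophagy receptor on the hypoxia list, rose (0.55), together with LOX, among 23 hypoxia genes, of which 6 rose and 3 fell when adjusted over the list alone. ATF3, a stress-induced transcription factor, fell (-0.57) and was the called member of 32 unfolded protein and integrated stress response genes. It also stands on the list of 32 immediate early genes, where BTG2 rose. Adjusted over the list alone, 1 rose and 3 fell among the former and 2 rose and 2 fell among the latter. SMN1 fell (-0.54) among 40 spliceosome genes, over all genes and adjusted over the list alone, but it has the near-identical copy SMN2, so its count is uncertain.

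**Figure D3:**
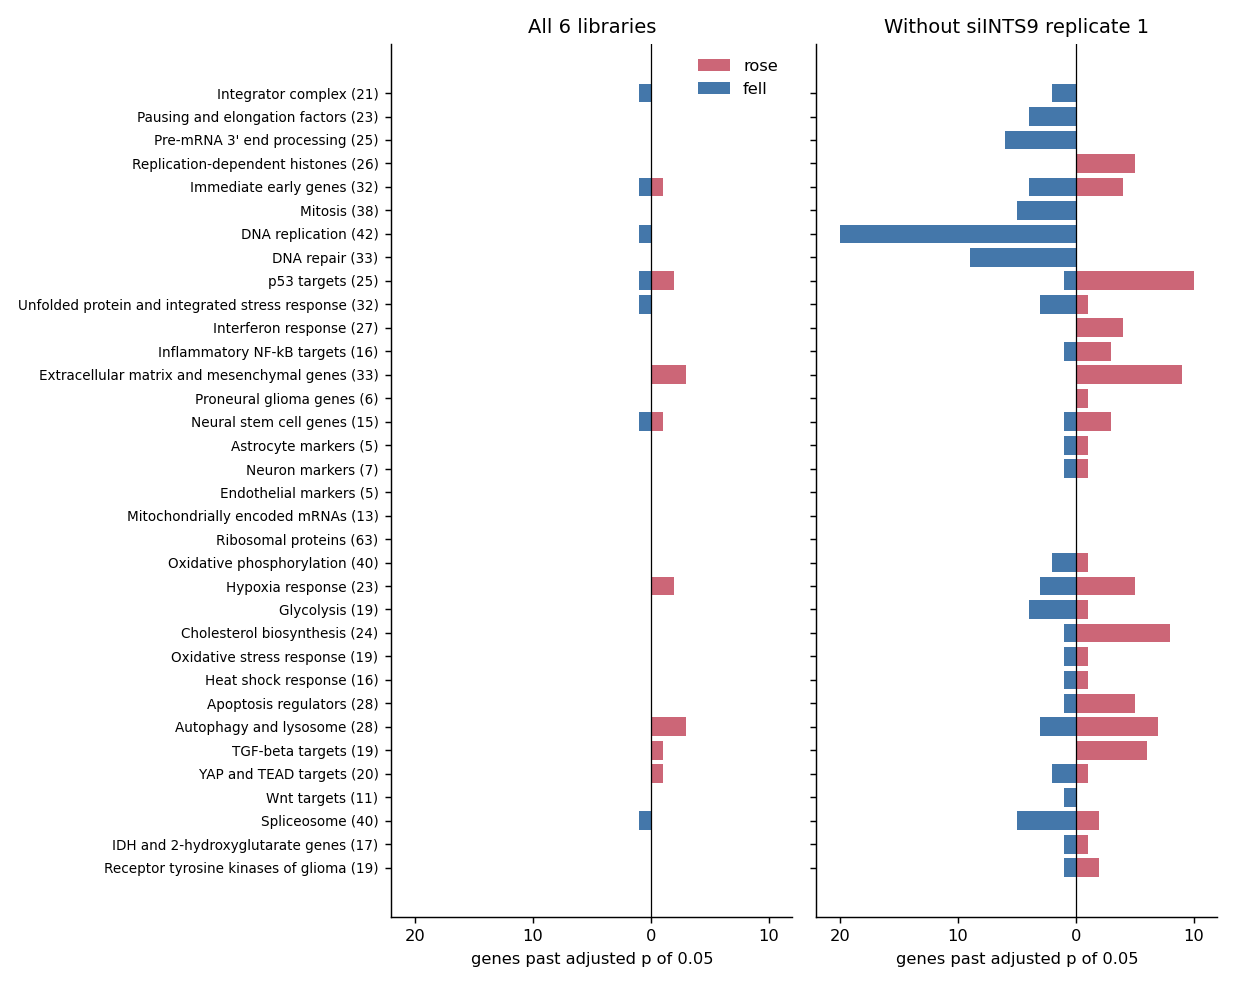
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test per gene list, higher (red, right of 0) and lower (blue, left of 0) in siINTS9 libraries, with all 6 libraries (left) and without siINTS9 replicate 1 (right), where numbers in brackets are genes tested with all 6 libraries. DNA replication had 1 gene lower with all libraries and 20 without that replicate.

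Replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, stood highest in siINTS9 replicate 1. Their summed level was 211, 197 and 195 CPM in control replicates 1 to 3, 1137 CPM in siINTS9 replicate 1, and 275 and 277 CPM in siINTS9 replicates 2 and 3. These sums used TMM factors over all listed genes, without the filter. None of the 26 tested was called with all 6 libraries, over all genes or adjusted over the list alone, and the median log2 was 1.70. When siINTS9 replicate 1 was left out the median was 0.44 and 5 genes rose, H1-2 (log2 0.62, adjusted p 0.00335), H2AC6, H2BC11, H2BC12 and H3C8 (0.94, adjusted p 0.0395). Camera placed the list higher at an adjusted p of 8.24e-04 with the preset correlation and 0.680 with an estimated correlation. It also did so without siINTS9 replicate 1 (adjusted p 5.10e-04; adjusted p 0.297 with an estimated correlation). Cytosolic ribosomal protein genes had a median log2 of -0.14 with all 6 libraries and 0.077 without siINTS9 replicate 1, with none of 63 called either way or when adjusted over the list alone with all 6, and camera's direction reversed (adjusted p 3.47e-04, lower, against 0.0110, higher). With an estimated correlation the adjusted p was 0.713 with all 6 libraries and 0.828 without that library. Nuclear respiratory chain genes had a median of -0.20 with all 6 libraries, where none of 40 was called over all genes or adjusted over the list alone, and -0.044 without that library, and camera's call (adjusted p 3.79e-04; 0.680 with an estimated correlation) was lost without it (0.551). In that fit NDUFB3 (0.33) rose and CYC1 (-0.37) and NDUFS7 (-0.32) fell.

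**Figure D4:**
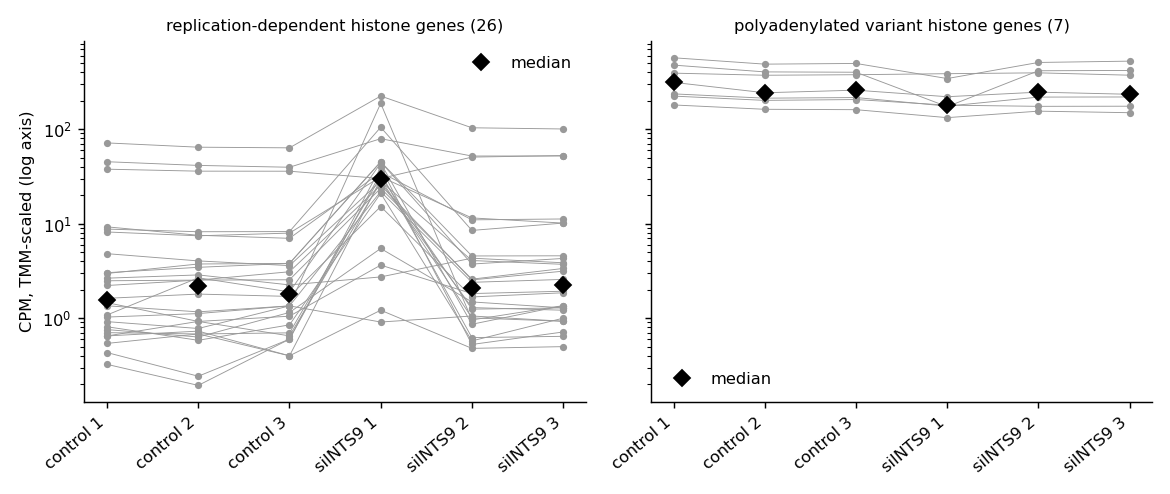
TMM-scaled CPM on a log axis for 26 replication-dependent histone genes (left) and 7 polyadenylated variant histone genes (right) in each of the 6 libraries. Grey lines join the values of a gene and black diamonds mark the median. The TMM factors were taken over all listed genes, without the filter. In siINTS9 replicate 1, 23 of the 26 replication-dependent genes were higher than in all other libraries, and none of the 7 variants was.

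In total, camera called 16 of 34 lists with the preset correlation, 7 higher and 9 lower. Other splits of the 6 libraries into 3 and 3 gave 6 to 12 called lists with that correlation. In the real split camera called none with an estimated correlation, where the lowest adjusted p was 0.418. Besides those described, it placed pre-mRNA 3' end processing (adjusted p 0.0356; adjusted p 0.418 with an estimated correlation), glycolysis (0.0241; adjusted p 0.603 with an estimated correlation) and spliceosome genes (0.0388; adjusted p 0.680 with an estimated correlation) lower. Of these, 3' end processing was still called without siINTS9 replicate 1 (adjusted p 0.0110; adjusted p 0.297 with an estimated correlation), while glycolysis (0.178) and spliceosome genes (0.418) were not. Among 25 genes of pre-mRNA 3' end processing none was called with all 6 libraries, over all genes or adjusted over the list alone, and SLBP, the histone stem-loop binding protein, had a log2 of -0.40 (adjusted p 0.168). In this list 6 genes fell without siINTS9 replicate 1, among them FIP1L1 and SLBP, each at -0.30. Higher lists were interferon response (0.0388; adjusted p 0.680 with an estimated correlation), cholesterol biosynthesis (0.00473; adjusted p 0.674 with an estimated correlation) and receptor tyrosine kinases of glioma (0.00968; adjusted p 0.680 with an estimated correlation), none with a called member over all genes tested. The receptor tyrosine kinase list lost its call without siINTS9 replicate 1 (camera's adjusted p 0.135), and the interferon (0.0109; adjusted p 0.421 with an estimated correlation) and cholesterol (5.02e-06; adjusted p 0.297 with an estimated correlation) lists did not. In those 5 libraries, over all genes tested, glycolysis had 1 rise and 4 falls and spliceosome genes 2 rises and 5 falls. The receptor tyrosine kinase list there had 2 rises, IGF1R (log2 0.41) and FGFR1 (0.30), and 1 fall, the phosphatase DUSP4 (-0.33). Glycolysis, likewise with no called member, had 1 rise (ALDOC, 0.53) and 3 falls (ENO2, PFKM and PFKL, -0.37, -0.38 and -0.32) when adjusted over the list alone, the interferon list had 1 rise (IFIT2, log2 0.90), and the cholesterol and receptor tyrosine kinase lists had none. Lists of pausing and elongation factors, NF-kB targets, proneural genes, oxidative stress, heat shock, apoptosis, Wnt targets and isocitrate dehydrogenase genes had no called member over all genes tested, and camera's adjusted p lay between 0.160 and 0.800. Among these, ICAM1 (log2 0.42), an adhesion molecule on the NF-kB list, NCAM1 (0.60), a neural adhesion molecule on the proneural list, and APAF1 (0.66) of the apoptosis list rose when adjusted over the list alone. Members of the pausing, oxidative stress, heat shock, Wnt and isocitrate dehydrogenase lists did not pass when adjusted over the list alone. Of the 23 pausing and elongation factors, 4 fell and none rose without siINTS9 replicate 1, CDK9 (-0.34), the kinase of P-TEFb, LEO1 (-0.32), HEXIM1 (-0.29) and ELL2 (-0.29).

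Markers of other cell types gave no called gene over all genes tested with all 6 libraries. Of the marker lists, 5 astrocyte, 7 neuron, 5 endothelial, 4 fibroblast, 4 epithelial, 3 oligodendrocyte genes and 1 microglia gene passed the expression filter. When each list was adjusted over the list alone, SLC1A3 rose (log2 0.44) and ALDH1L1 fell (-0.27) among astrocyte markers, SNAP25 (0.99) and NEFL (0.38) rose and ENO2 fell (-0.37) among neuron markers, PDGFRB (0.46) and THY1 (0.29) rose among fibroblast markers, and no marker of the others passed. In the fit without siINTS9 replicate 1, SLC1A3, an astrocyte glutamate transporter, rose (log2 0.38) and ALDH1L1 fell (-0.31), NEFL rose (0.44) and ENO2 fell (-0.41) among neuron markers, S100A4 (0.74) and THY1 (0.30) rose among fibroblast markers, and KRT8 rose (0.29) and ELF3 fell (-1.58) among epithelial markers. ELF3 had few counts, at 1.29 ± 0.191 CPM in control and 0.916 ± 0.826 CPM in siINTS9 libraries (SD, n = 3 each). With all 6 libraries its log2 was -1.06 (adjusted p 0.325 by edgeR's quasi-likelihood test). None of the 13 mitochondrially encoded mRNAs was called, with a median log2 of 0.035. Small nuclear RNA genes, the processing targets of Integrator, were not analysed here, since 0 of 30 on the list were among the listed genes.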

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

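The tests of genomic DNA, of poly(A) selection and of INTS9 were chosen after the result was seen, and that of depth after a first view had shown the library apart. No group holds 4 or more libraries and there is a single contrast, so the look for outlying samples and for groups that respond differently tested nothing here.

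The share of the library total behind RPKM that was not counted on listed genes exceeded the highest control share in each siINTS9 library. It was 88.9% in siINTS9 replicate 1, 14.7% in replicate 2 and 14.4% in replicate 3, against 10.4%, 13.2% and 14.3% in control replicates 1 to 3. The excess in siINTS9 replicates 2 and 3 is under 1 percentage point and is given as a value.

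siINTS9 replicate 1 also stood apart in its gene levels. After thinning all libraries to its depth, its root mean square log2 difference from siINTS9 replicates 2 and 3 was still 2.43 ± 0.023 times (SD over 20 thinnings) that between those libraries, which argues against low depth alone, and 1.96% of genes silent elsewhere (106 of 5412) had a count in it, which argues against genomic DNA as the main source. Replication-dependent histones lay above siINTS9 replicates 2 and 3 by a median log2 of 2.85 ± 0.392 (scaled median absolute deviation over the root of n), while 7 polyadenylated histone variants lay at -0.20, which is consistent with weaker poly(A) selection in that library. Across 9338 genes, which are not independent replicates, its deviation was higher for longer exons (Spearman's rho 0.612). A deeper knockdown stays open. INTS9 in siINTS9 replicate 1 was 0.792 times that of the other siINTS9 libraries, with an exact interval of 0.425 to 1.36 that includes equal levels. This ratio used TMM factors over all listed genes, without the filter, unlike the INTS9 CPM values given above. An effect of INTS9 loss on the ends of histone mRNAs stays open as untested.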

How the results depend on the processing

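Library weights, and tools other than edgeR's quasi-likelihood test without siINTS9 replicate 1, were chosen after the data were seen. Alternatives planned for files without counts (quantile normalization, other pseudocounts) were not run, since the files hold counts. The 119 calls of edgeR became 113 with RLE factors, 88 with library size alone, 175 with limma-voom and 169 with the 5 CPM filter. They became 782 with DESeq2 (398 higher, 384 lower), 63 with no filter, 33 with limma on deposited CPM and 0 on deposited TPM (1780 at an unadjusted p under 0.05). A fold test with glmTreat left 0 and an absolute log2 of at least 1 left 15. Library weights gave 2706, and 1324 with the replicate block. Leaving out a library gave 0 to 1426, the high value without siINTS9 replicate 1, where DESeq2 gave 1356 and limma-voom 1363. The common biological coefficient of variation was 0.138 with all 6 libraries and 0.0729 without it. The share of higher calls was 59.7% with all 6 and 49.4% without it. The cause of these differences was not tested.

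With the replicate number as a block, edgeR gave 0 calls (1248 at an unadjusted p under 0.05) and INTS9 had a log2 of -1.49 with an adjusted p of 0.446, while camera called the same 16 lists. Same-numbered libraries deviated against each other (correlations -0.28, -0.19 and -0.19), and none correlated best with its own number. Deviations from the mean of 3 libraries depend on each other, so this check cannot tell whether the numbers pair the libraries. INTS9 had a log2 of -1.29 (adjusted p 0.0599) on deposited TPM, and leaving out a library gave -1.54 to -1.44. Its adjusted p ranged from 3.26e-11 with DESeq2 to 0.446 over alternatives. All 24 genes named by the rule lost their call with the block, on TPM and in each leave-one-out other than siINTS9 replicate 1.

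Of 16 lists called, none held with an estimated correlation, with all 6 libraries or without siINTS9 replicate 1 (0 in both). Directional fry called 8 lists (6 of them among the 16), mixed fry 18 (8 among the 16), library weights 10 (9 among the 16) and the 5 CPM filter 12 (12 among the 16). By directional fry the 6 were 3' end processing (adjusted p 7.03e-04), extracellular matrix (0.0163), Integrator (0.0414), DNA replication (0.0429), DNA repair and p53 targets (0.0433 each). It also called NF-kB targets and hypoxia genes (0.0429 each). Unlike camera, fry does not compare a list with the other genes. Leaving out a library gave 11 to 16 lists by camera, of which 10 to 16 were among the 16, or 0 to 16 with the estimated correlation counted. Ribosomal proteins reversed from lower to higher without siINTS9 replicate 1 (median log2 0.080 on voom values, also with an estimated correlation; -0.41 to 0.080 over the libraries left out) and with library weights (0.083). The cause was not tested. Depth limits siINTS9 replicate 1 most, at 3083846 counts.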

Other observations

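The members named in the next paragraph, and the tests of the DNA replication genes without siINTS9 replicate 1 and of other splits, were chosen after the result was seen, while the test of exon length was fixed before its result was seen.

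In the 5 libraries without siINTS9 replicate 1, 1426 of 12340 genes tested were called, against 119 of 12256 with all 6 libraries. Several lists held more called genes than with all 6 libraries, where none of the genes named in this paragraph was called. Since calls rose over all genes, these counts alone do not set a list apart. Of 24 genes of cholesterol synthesis and uptake, 8 rose and 1 fell, with MSMO1 (log2 0.42) and HMGCS1 (0.42), enzymes of sterol synthesis, among the rises and INSIG1 (-0.28), a brake on the pathway, as the fall. Interferon-stimulated genes had 4 rises among 27, IFIT2 (0.93), an RNA-binding antiviral effector, DDX58 (0.39), a viral RNA sensor, BST2 and IFITM2. Of 16 NF-kB targets, CCL2 (1.31) and CXCL8 (0.99), a pair of chemokines, rose with ICAM1 (0.36), and LIF (-0.34) fell. CCL2 and CXCL8 were low, at 2.53 and 1.36 CPM in control libraries. Apoptosis regulators had 5 rises and 1 fall among 28, with BIK (0.56) among those higher and BCL2L11 (-0.69) lower. Immediate early genes had 4 rises and 4 falls among 32, with the transcription factors KLF6 (0.34) higher and EGR1 (-0.79) lower. The stress response list had 1 rise, SEL1L (0.36), and 3 falls, among them ASNS (-0.64), asparagine synthetase. IDH1, on the list of isocitrate dehydrogenases and 2-hydroxyglutarate genes, rose (0.44). With an estimated correlation, camera called none of these lists, at adjusted p values of 0.297 for cholesterol and 0.421 for interferon.

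DNA replication genes lay lower as a list by camera with the preset correlation, a call lost with an estimated correlation (adjusted p 0.418 with all 6 libraries and 0.297 without siINTS9 replicate 1), and 1 of 42 was called with all 6 libraries. Without siINTS9 replicate 1 the list median was -0.24 ± 0.016 (bootstrap SD over genes), with 40 of 42 genes below 0. The lower values in the other libraries argue against that library as the whole cause. The bootstrap treated the genes as independent and held the libraries fixed, so its SD does not measure the spread between libraries. After removing a smooth trend on exon length, also without siINTS9 replicate 1, the median was -0.23 ± 0.017 (same bootstrap). Fold change and exon length were nearly unrelated there (Spearman's rho 0.038), so removal could move the median little. These values argue against a length trend as the whole cause without that library alone. The median with all 6 libraries was not corrected for exon length. An effect of INTS9 loss, off-target effects of the siRNA and differences between cultures stay open as untested.

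For the number of genes called, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 119, and the highest of the others gave 0. For gene lists, 1 of 10 splits gave as many as 16, and the others gave 6 to 12. Camera with the preset correlation thus also called lists when control and siINTS9 libraries were mixed. Without siINTS9 replicate 1, 1 of 10 splits gave as many as 1426, and the highest of the others gave 1. These 10 splits are too few for a share under 0.05.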
